A study of Mus musculus and Homo sapiens with 21 samples.

How the data were processed

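Poly(A) RNA had been sequenced with a SMARTer mRNA-Seq kit from human A549 cells and from mouse OT-1 CD8+ T cells, per the labels. The strand kept by the libraries is not stated, so reads of overlapping genes on opposite strands may be shared. The tables deposited by the authors hold estimated counts per gene symbol, which their processing notes place after STAR 2.6.1d and Salmon 0.13.1, with no further normalization. Those notes name only mouse builds (GRCm38 and mm10), so the build and annotation behind the human table are not given in the sources used here. The authors also deposited 2 tables of DESeq2 1.34.0 results, which give a log2 fold change for each gene. These deposited tables of the authors also give a p-value and an adjusted p-value for each gene, with the design formula not stated. They served only for a comparison at the end.

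The deposited counts name 58387 genes in A549 and 55291 in OT-1, and 0 columns were left unused. The 9 A549 libraries form 3 groups of 3 (control guide and 2 guides against the target). The columns of the 9 OT-1 libraries were matched to the co-cultured groups through the guide in the column name and the title of the table, since the control columns do not name the condition. The 3 untreated OT-1 libraries were not used here, so the planned comparison of co-cultured with untreated control cells was not made.

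Counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 15310 genes in A549 and 13380 in OT-1, and libraries were scaled by TMM. CPM, the counts scaled to library size, use the scaled library sizes, and logarithms of them a prior count of 2. The spread was estimated by estimateDisp and glmQLFit, and groups were compared by glmQLFTest with Benjamini-Hochberg adjustment at 0.05. Both guides together were set against the control (6 libraries against 3), then each guide against the control and the guides against each other in a fit of 3 groups. The standard error of a log2 change is its absolute value divided by the square root of the F statistic. DESeq2 1.42.0 served as a second test.

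Comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, unless stated otherwise. The rule named the targeted gene, the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM and the same sign at an unadjusted p under 0.05 with each guide, and the 3 members of each list with the lowest p. It also named the 3 largest called differences per direction between the guides, and up to 6 genes per direction called in both cell kinds, and it passed over clone names and unnamed predicted genes. Some of these are left out of the text for length, and 1 OT-1 gene named by the rule is not reported here, though counts over the named genes include it. KRT18 in A549, the genes named as called in opposite directions in the 2 cell kinds and the members named of a second list of adherent-cell genes were chosen after their values were seen. There were 16 gene lists for A549 and 23 for OT-1, those of other cell types included, and camera from limma 3.58.1 tested each list with at least 3 tested members at a preset correlation of 0.01, with an estimated correlation and with fry beside it. The test fry asks whether the genes of a list move, on balance, one way, without comparing them with other genes. Genes called in both cell kinds were counted over symbols equal regardless of case and tested by Fisher's exact test.

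Alternatives fixed in advance were DESeq2 size factors, no filter, a filter of 5 CPM in at least 3 libraries, DESeq2, a threshold of 0.01, a replicate block, the mean of the guide effects, and leaving out each library in turn. After the data had been seen, a GC correction, a fit without mitochondrial genes and the ribosomal RNA locus CT010467.1, the omission of the OT-1 libraries with the highest and lowest mitochondrial share, and, in A549, a covariate for the main direction of spread within guides were added. The GC correction was a loess (span 0.4, degree 1) of each library's log2 deviation on the GC content of GENCODE mouse M21 transcripts, fitted on genes with a mean log2 CPM over 1, and covered 98.3% of the OT-1 genes tested. No human genome was at hand, so the same check was not made for A549. Every other split of the libraries into groups of the same sizes was also tested. The correlation that shared controls alone give between the guides was taken from 20 simulations.

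The fits were tested on simulated data with 200 changed genes. In A549, knockout against control, 68% of changes of 0.5 and 98% of changes of 1 on the log2 scale were recovered, and 7.26% of calls were false (14.1% with DESeq2). In OT-1, 29% and 85% were recovered with 8.06% false calls (19.6% with DESeq2). With a simulated GC trend 81.8% of the OT-1 calls were false, and 5.36% after the correction. Recovery of changes of 0.5 was 39% before the correction and 22% after it, and of changes of 1 it was 83% and 84%. The simulated trend was a straight line on the GC content that the correction fits, and the changed genes were drawn without regard to it. It therefore cannot show whether the correction takes out real changes that go with GC content. In simulated A549 data with no effect but with a hidden factor shared by some libraries, 1 of 20 simulations called at least 170 genes between knockout and control, and with the covariate the comparison of the guides gave a median of 465 false calls. Results with that covariate are therefore given only as values.

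Mitochondrial genes took 13.7% to 15.4% of the counts in A549. In OT-1 they took 1.38% to 2.89% in the controls, highest in sgCtrl replicate 1, and 0.346% to 1.35% in the libraries labelled knockout, lowest in sgTnfaip3-2 replicate 1. Genes of ribosomal proteins took 6.92% to 9.10% and 9.11% to 10.6%. The composition of the OT-1 libraries thus moved with the labels, and the fit without mitochondrial genes takes out their counts but not what lies behind their share. The locus CT010467.1 took 1.56% and 1.10% in sgCtrl replicates 1 and 2 and 0.0311% to 0.347% in the other libraries. Replicates were not copies of each other, with a chi-square per degree of freedom between pairs of 2.43 to 58.8.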

Results

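Messenger RNA was sequenced from A549 cells, a human lung adenocarcinoma line, and from OT-1 cells, mouse CD8+ T cells that carry a T-cell receptor for an ovalbumin peptide. Both had received CRISPR guides against TNFAIP3 (Tnfaip3 in the mouse), which encodes A20, a ubiquitin-editing protein that restrains NF-kB signalling downstream of the TNF receptor. The stated aim was to learn what the gene does in cancer cells that face T-cell killing and in the T cells themselves. The series holds 21 libraries in 7 groups of 3. In each cell kind a control guide (sgCtrl) was set against 2 guides for the target (sgTNFAIP3-1 and sgTNFAIP3-2 in A549, sgTnfaip3-1 and sgTnfaip3-2 in OT-1), and the OT-1 cells of these groups had been cultured with cancer cells of a kind the labels do not name. The 3 untreated OT-1 libraries were not analysed here, so all comparisons rest on 18 libraries. Estimated counts summed to between 16602465 and 18044564 in the 9 A549 libraries and between 15436320 and 18138613 in the 9 OT-1 libraries. At these depths 3 counts, the level that a count of 0 still allows, correspond to 0.166 to 0.181 CPM (counts scaled to the library total) in A549 and 0.165 to 0.194 CPM in OT-1. Floors of this kind cover counting error only. The labels do not say that replicates were separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

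The mRNA of the targeted gene was higher in the A549 libraries labelled knockout, and slightly lower in those of OT-1 without passing the main test. In A549, TNFAIP3 stood at 31.5, 32.4 and 27.9 CPM in the sgCtrl libraries, at 46.3, 40.5 and 39.1 CPM with sgTNFAIP3-1 and at 48.8, 48.0 and 44.8 CPM with sgTNFAIP3-2. It was thus higher in the libraries labelled knockout, by 0.54 on the log2 scale (SE 0.0875, n = 6 against 3, edgeR adjusted p = 0.00595), and this call was lost without sgCtrl replicate 3 (adjusted p = 0.0654). In the authors' deposited table the log2 change of TNFAIP3 was 0.349 with an adjusted p of 0.28. In OT-1, Tnfaip3 (chromosome 10, 19000910 to 19015657, GRCm38) stood at 909, 897 and 885 CPM with sgCtrl, at 817, 806 and 821 CPM with sgTnfaip3-1 and at 843, 822 and 832 CPM with sgTnfaip3-2, a log2 difference of -0.12 (SE 0.058) that did not pass the test (edgeR adjusted p = 0.144). All 6 libraries labelled knockout lay under all 3 controls, and DESeq2 called the gene lower (log2 -0.13, adjusted p = 0.0105). The authors' deposited DESeq2 results did not call it (log2 -0.0878, adjusted p = 0.156). Counts summed over a gene do not show whether its reading frame was broken, so these values do not check the labels. The libraries are therefore called by their labels throughout, and every direction below is between labels.

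**Figure D1:**
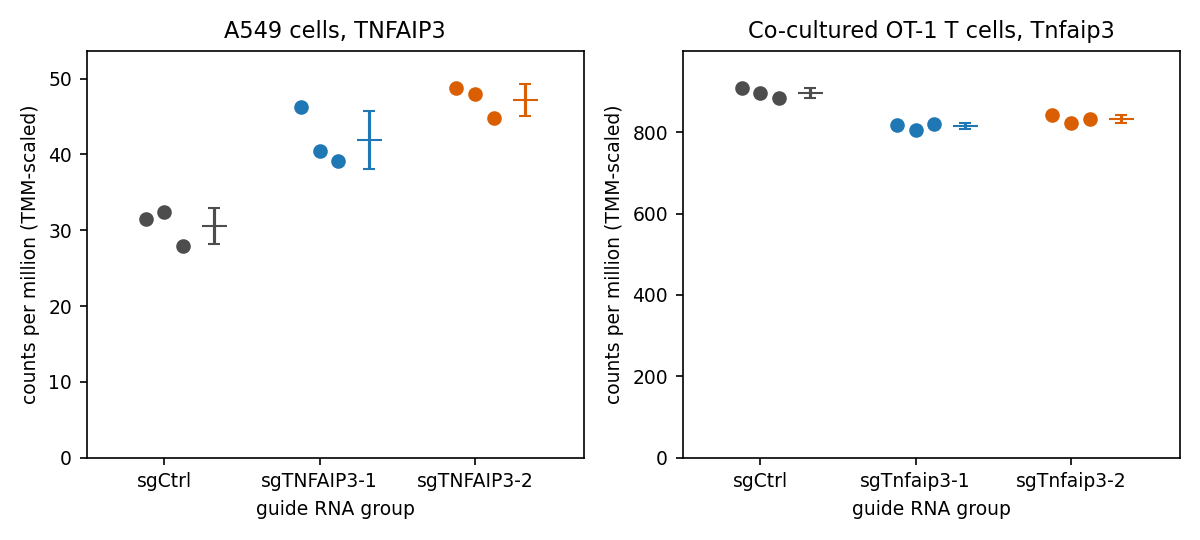
Expression in CPM of TNFAIP3 in the 9 A549 libraries (left) and of Tnfaip3 in the 9 co-cultured OT-1 libraries (right) by guide, with each point 1 library and the bars the mean and SD of 3. In A549 the libraries labelled knockout lie between 39.1 and 48.8 CPM, above the controls, which reach at most 32.4 CPM.

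In A549 cells the libraries labelled knockout contained more mRNA of several inflammatory mediators than the controls. CCL5, a chemokine that attracts T cells, rose from 1.61 ± 0.256 CPM (SD, n = 3) to 9.16 ± 1.63 CPM (SD, n = 6), a log2 change of 2.50 (SE 0.193). CCL20, a chemokine of the mucosa, rose from 4.51 ± 0.795 to 12.8 ± 1.27 CPM, and ICAM1, an adhesion ligand for leukocyte integrins, from 12.5 ± 0.977 to 28.6 ± 2.01 CPM. The neuropeptide precursor NTS rose by 1.23 on the log2 scale, the cytokine IL6 by 1.21 and the transcriptional regulator ID4 by 0.93. Among the genes that fell, the tight-junction protein CLDN2 went from 51.2 ± 2.44 to 25.3 ± 3.27 CPM and the transcriptional cofactor LBH from 64.3 ± 4.90 to 32.1 ± 1.97 CPM. The adhesion molecule CEACAM6 fell by 0.99 on the log2 scale, and the neurotrophic factor receptor GFRA1 fell by 0.98. PRR15 (log2 -0.99) and the sulfotransferase SULT1A3 (log2 -1.16), which has a near-identical copy whose reads it shares, also passed the test. By edgeR's quasi-likelihood test, 80 of 15310 genes were higher and 90 lower at an adjusted p under 0.05, of which 15 and 11 differed by at least 2-fold. The adjusted p of CCL5 was 2.38e-05 and that of LBH 2.32e-05. The count of 170 was 294 by DESeq2, and 84, 447 and 64 without sgCtrl replicates 1, 2 and 3. A grouping of sgCtrl replicate 2 with sgTNFAIP3-1 replicates 1 and 3 against the other 6 libraries called 3347 genes. The call of SULT1A3 was lost in 10 of 17 alternative settings and that of PRR15 in 7, without sgCtrl replicate 1 or 3 among them.

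**Figure D2:**
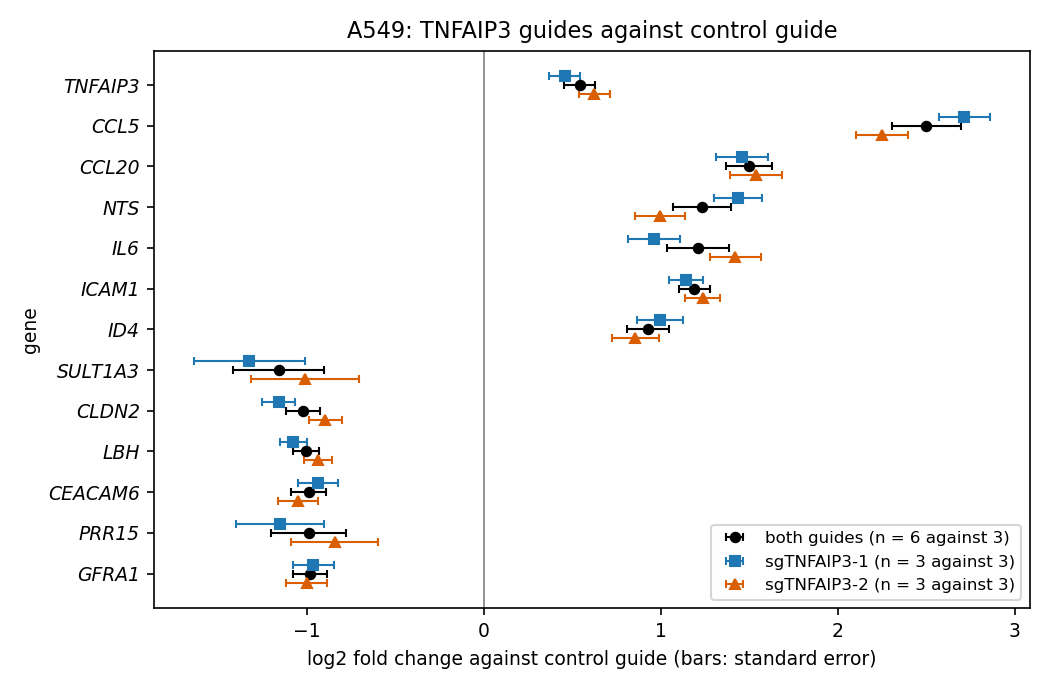
Log2 fold changes against the control guide for TNFAIP3 and the 12 largest called changes among A549 genes with a mean of at least 5 CPM, over both guides (circles, n = 6 against 3) and for each guide alone (squares and triangles, n = 3 against 3), with bars for the standard error. Of these genes CCL5 has the largest rise (2.50), and for each gene the 2 guides lie on the same side of 0.

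Grouped by function, targets of NF-kB moved together in A549. Of 30 such genes 12 rose and 0 fell, and 26 were higher when adjusted over the list alone. Examples are CCL20 (log2 1.5, SE 0.132), ICAM1 (log2 1.19, SE 0.0891) and the mitochondrial superoxide dismutase SOD2 (log2 0.60, SE 0.0591). The set test camera gave an adjusted p of 1.22e-56, and 1.33e-05 with an estimated correlation. Of 27 interferon-response genes 3 rose, namely the antiviral GTPase MX1 (log2 1.05, SE 0.176), IFI6 (log2 0.86, SE 0.157) and GBP1 (log2 0.99, SE 0.199), 0 fell, and 11 were higher when adjusted over the list alone (camera adjusted p = 4.81e-11, and 0.00248 with an estimated correlation). Among 23 ubiquitin and TNF-receptor regulators, TNFAIP3 itself and the ubiquitin ligase BIRC3 (log2 0.55, SE 0.113) rose, also when adjusted over the list alone (camera adjusted p = 0.000188, and 0.015 with an estimated correlation). Epithelial genes moved both ways and lower on balance. Of 14, the keratins KRT19 (log2 -0.67, SE 0.0746) and KRT8 (log2 -0.28, SE 0.0517) and KRT18 (log2 -0.21, SE 0.0473, named after its value was seen) fell while the tight-junction gene CLDN1 rose (log2 0.43, SE 0.0777). When adjusted over the list alone 1 was higher and 6 lower (camera adjusted p = 0.00119, and 0.0275 with an estimated correlation). Without sgCtrl replicate 1 the calls of MX1, IFI6, GBP1, BIRC3, CLDN1 and KRT8 were lost, with adjusted p over all named genes so lost between 0.0536 and 0.189. Without sgCtrl replicate 3 the same 6 were lost with others, between 0.0654 and 0.258. With the replicate block IFI6, GBP1, BIRC3, CLDN1 and KRT8 were lost with others, between 0.0533 and 0.151.

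Other A549 lists were called by camera at its preset correlation but not with an estimated one. Early genes of the MAP kinase pathway were higher, with the phosphatase DUSP6 (log2 0.47, SE 0.0665) and PHLDA1 (log2 0.27, SE 0.0544) called among 20 and 6 higher when adjusted over the list alone (camera adjusted p = 3.4e-06, but adjusted p = 0.0811 with an estimated correlation). Mesenchymal genes were lower, with the matrix glycoprotein SPARC the 1 called of 19 (log2 -0.56, SE 0.108) and 4 lower when adjusted over the list alone (camera adjusted p = 0.00124, but adjusted p = 0.0796 with an estimated correlation). NRF2 targets were lower, with the aldo-keto reductases AKR1B10 (log2 -0.46) and AKR1C3 (log2 -0.29) called among 18 and 4 lower when adjusted over the list alone (camera adjusted p = 0.00472, but adjusted p = 0.38 with an estimated correlation, and 0.0582 by camera without sgCtrl replicate 2). Of 3 fibroblast markers tested 0 were called and 1 was lower when adjusted over the list alone, with THY1 at log2 -0.33 and LUM at log2 -0.43 (camera adjusted p = 0.0143, but adjusted p = 0.0796 with an estimated correlation, and 0.107 by camera without sgCtrl replicate 2). Of the genes named here, SPARC and AKR1C3 lost their calls without sgCtrl replicate 3, as did PHLDA1, which also lost it without sgCtrl replicate 1 and without 3 of the libraries labelled knockout, with adjusted p at most 0.258. SPARC and PHLDA1 also lost it with the replicate block (0.0762 and 0.0846).

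The remaining A549 lists did not pass. No gene was called among 20 of MHC class I presentation (camera adjusted p = 0.107), 25 of cell death (0.111), 9 checkpoint ligands (0.195), 20 p53 targets (0.919), 18 of the ATF4 stress response (0.296), 24 of the cell cycle (0.696) and 4 leukocyte markers (0.919). The glucose transporter SLC2A1 was the 1 called of 20 hypoxia and glycolysis genes (log2 -0.32, SE 0.0665, list 0.919). The count adjusted over the list alone was 0 higher and 1 lower for checkpoint ligands and for hypoxia, 1 higher and 1 lower for p53 targets and 0 for the others. The antigen transporter TAP1 had a log2 change of 0.28 (SE 0.0848, edgeR adjusted p = 0.183), the ecto-nucleotidase NT5E of -0.35 (SE 0.0873, 0.0894) and the stress cytokine GDF15 of 0.30 (SE 0.0884, 0.176). Checkpoint ligands passed the rotation test fry downward (adjusted p = 0.00542). The MHC class I list passed camera without sgCtrl replicate 3 (adjusted p = 0.0144) or sgTNFAIP3-1 replicate 1 (0.0418), and the call of SLC2A1 was lost in 9 of 17 settings, among them without sgCtrl replicate 1 or 3 and with the replicate block.

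Each A549 guide was also set against the control alone. CCL5 rose by 2.71 on the log2 scale with sgTNFAIP3-1 and by 2.25 with sgTNFAIP3-2, and ICAM1 by 1.14 and 1.24. NF-kB targets rose with both, 12 of 30 with sgTNFAIP3-1 and 9 of 30 with sgTNFAIP3-2, with 0 lower (20 and 22 when adjusted over the list alone, camera adjusted p = 6.68e-43 and 8.67e-53, and 0.000415 and 0.000213 with an estimated correlation). Of the lists camera called with 1 guide only, mesenchymal genes were lower with sgTNFAIP3-1, 0 of 19 higher and 1 lower (0 and 6 when adjusted over the list alone, camera 8.06e-05, and 0.0177 with an estimated correlation, against camera 0.0544 with sgTNFAIP3-2). The mesenchymal list did pass fry with sgTNFAIP3-2 (adjusted p = 0.0186). Cell-death genes were higher with sgTNFAIP3-1, with 0 of 25 called, also when adjusted over the list alone (camera 0.0498, but adjusted p = 0.162 with an estimated correlation, against camera 0.472). NRF2 targets were lower with sgTNFAIP3-2, 0 of 18 higher and 2 lower (0 and 4 when adjusted over the list alone, camera 2.11e-05, but adjusted p = 0.117 with an estimated correlation, against camera 0.571 with sgTNFAIP3-1). So were the 3 fibroblast markers, with 0 called, also when adjusted over the list alone (camera 0.037, but adjusted p = 0.117 with an estimated correlation, against camera 0.0602). With sgTNFAIP3-1 these markers did pass camera with the replicate block (adjusted p = 0.0477) and fry (0.00168). With sgTNFAIP3-1, 75 genes were higher and 112 lower by edgeR (187, and 287 by DESeq2), and with sgTNFAIP3-2, 60 were higher and 49 lower (109, and 192 by DESeq2). Of these, 41 genes were higher and 33 lower with both guides, where independent lists would share 0.294 and 0.358, and 0 were called in opposite directions. Between the guides edgeR called 0 genes, 1273 had an unadjusted p under 0.05, and DESeq2 called 14. Camera placed mesenchymal genes higher (adjusted p = 0.0452, but adjusted p = 0.381 with an estimated correlation) and NRF2 targets lower (0.0031, but adjusted p = 0.556 with an estimated correlation) with sgTNFAIP3-2, with 0 members called in either and 1 mesenchymal gene higher and 1 lower when adjusted over the list alone. The mesenchymal list lost its call with the replicate block (camera adjusted p = 0.0685), and NRF2 targets did not pass fry (0.0658). Both guides were compared with the same 3 controls, too few to be split, so part of the overlap may come from them. The correlation of the log2 changes across genes was 0.47, against 0.50 in 20 simulations with no effect, and their covariance 0.0386 against 0.026 (genes are not independent replicates). Those simulations held no hidden structure among the libraries. A split that set sgCtrl replicate 2 and sgTNFAIP3-1 replicates 1 and 3 apart called 3347 genes. Such a structure could also raise the covariance through the shared controls. Without sgCtrl replicates 1, 2 and 3 the sgTNFAIP3-1 count was 92, 2119 and 73, and the sgTNFAIP3-2 count was 61, 276 and 46. It was also 91, 98 and 64 without sgTNFAIP3-1 replicates 1, 2 and 3, and 117 without sgTNFAIP3-2 replicate 2, for the first guide, and 35, 39 and 43 without sgTNFAIP3-2 replicates 1, 2 and 3 for the second. Between the guides it was 46 without sgCtrl replicate 2 and 1 without sgTNFAIP3-2 replicate 3.

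In the co-cultured OT-1 libraries labelled knockout the mRNA of Ifng and other genes was higher than in the controls. Ifng, the interferon made by activated T cells (chromosome 10, 118441046 to 118445892, GRCm38), rose from 857 ± 13.5 CPM (SD, n = 3) to 2019 ± 173 CPM (SD, n = 6), a log2 change of 1.24 (SE 0.0897). The cytokine Il24 rose from 2.03 ± 0.347 to 7.88 ± 1.67 CPM and the matrix glycoprotein Thbs1 from 2.94 ± 0.863 to 10.4 ± 1.45 CPM. Thbs1 is also a gene of adherent cells, several markers of which rose in these libraries. The basement-membrane protein Tinagl1 rose by 1.92 on the log2 scale, the neuron navigator Nav3 by 1.85 and the actin cross-linker Flnc by 1.84. The adaptor Sh2d1b2 fell from 42.5 ± 8.04 to 16.3 ± 2.21 CPM, and the lectin-like receptor Klrb1b from 10.6 ± 0.443 to 4.28 ± 0.570 CPM. Scel fell by 1.37 on the log2 scale, the arrestin-domain protein Arrdc3 fell by 1.16 and the purinergic receptor P2ry12 fell by 1.14. Rn7sk, a small nuclear RNA without a poly(A) tail, had the largest called fall among genes with a mean of at least 5 CPM (log2 -3.58, SE 1.13), but it stood at 78.6 ± 68.7 CPM in the controls, its groups overlapped, and the call was lost in 11 of 20 settings. By edgeR's quasi-likelihood test 1458 of 13380 genes were higher and 954 lower at an adjusted p under 0.05, of which 483 and 64 differed by at least 2-fold. The adjusted p of Ifng was 3.37e-05 and that of Il24 0.000203. The log2 change correlated with the GC content of the transcript across genes (rho 0.51), and with a per-library GC correction 3662 genes were called, 2156 of them among the original 2412. Setting the sgTnfaip3-2 libraries against the other 6 called 4493 genes. The count was 913, 1012, 1369 and 1468 without sgCtrl replicate 1, sgCtrl replicate 2, sgTnfaip3-2 replicate 2 and sgTnfaip3-2 replicate 3, and 1407 without sgCtrl replicate 1 and sgTnfaip3-2 replicate 1, whose mitochondrial shares of 2.89% and 0.346% were the highest and lowest. That share was 1.38% to 2.89% in the controls and 0.346% to 1.35% in the libraries labelled knockout, so it moved with the labels. The call of P2ry12 was lost without sgCtrl replicate 1 (adjusted p = 0.0879).

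**Figure D3:**
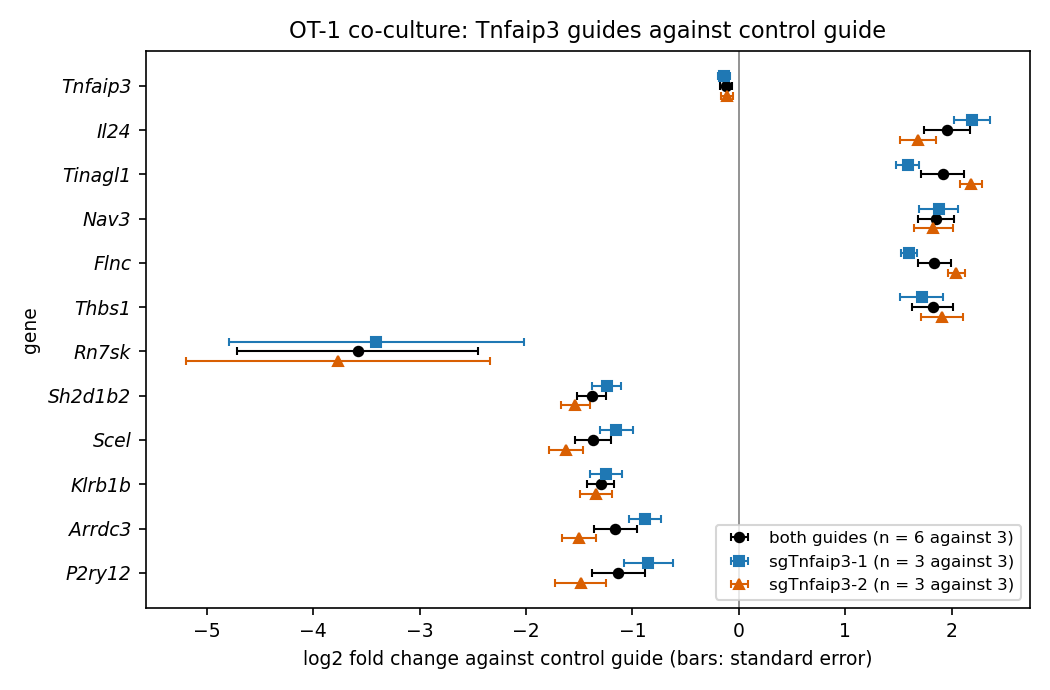
Log2 fold changes against the control guide for Tnfaip3 and 11 of the 12 largest called changes among OT-1 genes with a mean of at least 5 CPM, over both guides (circles, n = 6 against 3) and for each guide alone (squares and triangles, n = 3 against 3), with bars for the standard error. Tnfaip3 lies at -0.12, and Rn7sk has a standard error of 1.13.

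Cytokine and chemokine genes moved one way in the OT-1 libraries. Markers of other cells, given below, rose in the same libraries, so the counts do not show which cells made these mRNAs. Of 20 tested, 13 rose and 0 fell (15 and 0 when adjusted over the list alone), among them the macrophage growth factor Csf1 (log2 1.43, SE 0.136), the T-cell attractant Cxcl10 (log2 1.22, SE 0.110) and Lif (log2 1.12, SE 0.0961). The camera adjusted p was 1.72e-14, and 0.00558 with an estimated correlation. Of 24 cytotoxic and effector genes, 2 rose and 4 fell (5 and 8 when adjusted over the list alone), with Ifng higher, the inhibitory lectin Klrg1 lower (log2 -0.81, SE 0.0856) and the granzyme Gzmf lower (log2 -0.52, SE 0.102, in a cluster of similar genes). The list did not pass (camera adjusted p = 0.574). Inhibitory receptors went both ways, 4 of 18 higher and 3 lower (4 and 4 when adjusted over the list alone, camera 0.965), with Tigit at log2 0.65 and Lag3 at 0.62 against Entpd1 at -0.66. So did naive and memory genes, 5 of 19 higher and 3 lower (5 and 5 when adjusted over the list alone, camera 0.965), with Ccr7 at log2 0.83 and Lef1 at -0.79. Of activation receptors 3 of 21 were higher and 4 lower (4 and 5 when adjusted over the list alone, camera 0.519), with Cd44 at log2 0.45 and Cd69 at -0.80. Chemokine receptor and adhesion genes had 3 of 16 higher and 3 lower (4 and 4 when adjusted over the list alone, camera 0.965), with Vcam1 at log2 1.46 and the integrin Itga1 at -0.84. For inhibitory receptors, naive and memory genes and chemokine receptors the median log2 change was negative and the camera direction upward.

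Targets of NF-kB in OT-1 went both ways. Of 27, 7 rose and 3 fell (14 and 3 when adjusted over the list alone), with Tnfaip2 at log2 1.43 (SE 0.170) and the subunit Nfkb1 at log2 0.43 (SE 0.0768) among the higher ones. The camera adjusted p was 0.00476, but adjusted p = 0.378 with an estimated correlation. The same held for cell-cycle genes, with 7 of 24 higher and 0 lower (11 and 0 when adjusted over the list alone) and the mitotic kinases Aurkb (log2 0.78) and Aurka (log2 0.48) among them (camera 0.00476, but adjusted p = 0.456 with an estimated correlation). MHC class I genes had 5 of 21 higher and 0 lower (6 and 0 when adjusted over the list alone), with the transactivator Nlrc5 at log2 0.42 (camera 0.0357, but adjusted p = 0.483 with an estimated correlation, and 0.0538 by camera with the GC correction). Glycolysis and hypoxia genes had 5 of 21 higher and 0 lower (5 and 2 when adjusted over the list alone), with the hexokinase Hk2 at log2 0.99 (camera 0.0225, but adjusted p = 0.416 with an estimated correlation, and 0.134 by camera with the GC correction). Without sgCtrl replicate 1 the camera p was 0.0844 for the MHC class I and 0.0594 for the glycolysis list. Genes of IL-2 and STAT5 signalling had 8 of 21 higher and 4 lower (9 and 5 when adjusted over the list alone, camera 0.0784), with Socs3 at log2 1.19 (SE 0.105). That list passed camera without sgCtrl replicate 1 (adjusted p = 0.0482), sgTnfaip3-2 replicate 1 (0.0388) or sgTnfaip3-2 replicate 2 (0.0424), and it passed fry (0.0029). It passed neither test with the GC correction, where 5 were higher and 6 lower (camera adjusted p = 0.3, fry adjusted p = 0.11). Interferon-response genes had 7 of 30 higher and 2 lower (7 and 4 when adjusted over the list alone, camera 0.365), with Cxcl9 at log2 1.22 and Irf1 at 0.68. Cell-death genes had 2 of 25 higher and 2 lower (2 and 2 when adjusted over the list alone, camera 0.327), with Tnfrsf1a at log2 0.62 and Bcl2l11 at -0.34. The p53 targets had 1 of 19 higher and 3 lower (3 and 5 when adjusted over the list alone, camera 0.397), with Mdm2 at log2 -0.47. Of TNF-receptor ubiquitin regulators 2 of 26 were higher and 3 lower (2 and 3 when adjusted over the list alone, camera 0.332), with Tnip2 at log2 0.59 and Tax1bp1 at -0.49. Tax1bp1 was not called with the GC correction (adjusted p = 0.111). Of the named OT-1 genes 22 lost their call without sgCtrl replicate 1 (adjusted p 0.0592 to 0.167, among them Cd69, Aurkb, Aurka, Mdm2, Bcl2l11, Tnip2 and Tax1bp1), 19 without sgCtrl replicate 2 (0.0638 to 0.155) and 8 without sgCtrl replicate 3 (0.0503 to 0.11). There were 11 such genes without sgTnfaip3-2 replicate 2 (0.0538 to 0.0845) and 11 without sgTnfaip3-2 replicate 3 (0.0525 to 0.0975). With the replicate block there were 12 (0.0503 to 0.0949), among them Bcl2l11, Tnip2 and Tax1bp1.

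Markers of cells other than CD8+ T cells were tested in the OT-1 libraries too. Of 8 mesenchymal genes 4 rose and 0 fell (4 and 0 when adjusted over the list alone), among them the collagen Col3a1 (5.26 ± 0.743 to 16.5 ± 1.73 CPM), fibronectin Fn1 (5.32 ± 0.465 to 15.5 ± 2.20 CPM) and Sparc (10.1 ± 0.367 to 26.6 ± 3.6 CPM). The camera adjusted p was 3.59e-07, but adjusted p = 0.105 with an estimated correlation. Of 6 epithelial genes the keratins Krt8 (8.82 ± 0.561 to 26.8 ± 4.28 CPM) and Krt18 (log2 1.53, SE 0.169) rose and Epcam fell (log2 -0.45, SE 0.13). When adjusted over the list alone 3 were higher and 2 lower (camera 0.0357, but adjusted p = 0.378 with an estimated correlation, and 0.083 by camera without sgCtrl replicate 3). Of 4 natural killer cell markers, which activated CD8+ T cells can also express, the receptor Klrb1c (log2 -1.13, SE 0.0954) and the signalling adaptors Fcer1g (log2 -0.86, SE 0.0942) and Tyrobp (log2 -0.64, SE 0.150) fell, also when adjusted over the list alone (camera 1.02e-05, and 0.0186 with an estimated correlation). Of 6 myeloid markers Csf1r (log2 2.16, SE 0.485) and Cd74 rose and the Fc receptor Fcgr3 fell (log2 -1.06, SE 0.105), with 3 higher and 2 lower when adjusted over the list alone, a positive median and a downward camera direction (camera 0.574). Of 3 melanocyte markers Gpnmb rose (log2 1.76, SE 0.267), also when adjusted over the list alone (camera 0.209, fry 0.00268). Of 4 CD4+ T-cell markers Tnfrsf8 and Ikzf2 fell, also when adjusted over the list alone (camera 0.137, fry 0.00178), while Cd4 itself stood at 4.5 ± 0.757 and 5.01 ± 1.29 CPM. Ighm was the 1 B-cell marker tested and was not called (log2 -0.33, SE 0.3, edgeR adjusted p = 0.432), and 0 of 6 erythroid markers were detected well enough to be tested. Calls were lost for Csf1r, Cd74, Epcam and Ikzf2 without sgCtrl replicate 1 (adjusted p 0.0592 to 0.167 over all named genes so lost), for these and Tyrobp without sgCtrl replicate 2 (0.0638 to 0.155), for Cd74, Epcam and Ikzf2 without sgCtrl replicate 3, and for Cd74 and Epcam with the replicate block (0.0753 and 0.0785). With the GC correction the mesenchymal list passed with an estimated correlation as well (adjusted p = 0.025), and Ikzf2 was not called (adjusted p = 0.187).

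**Figure D4:**
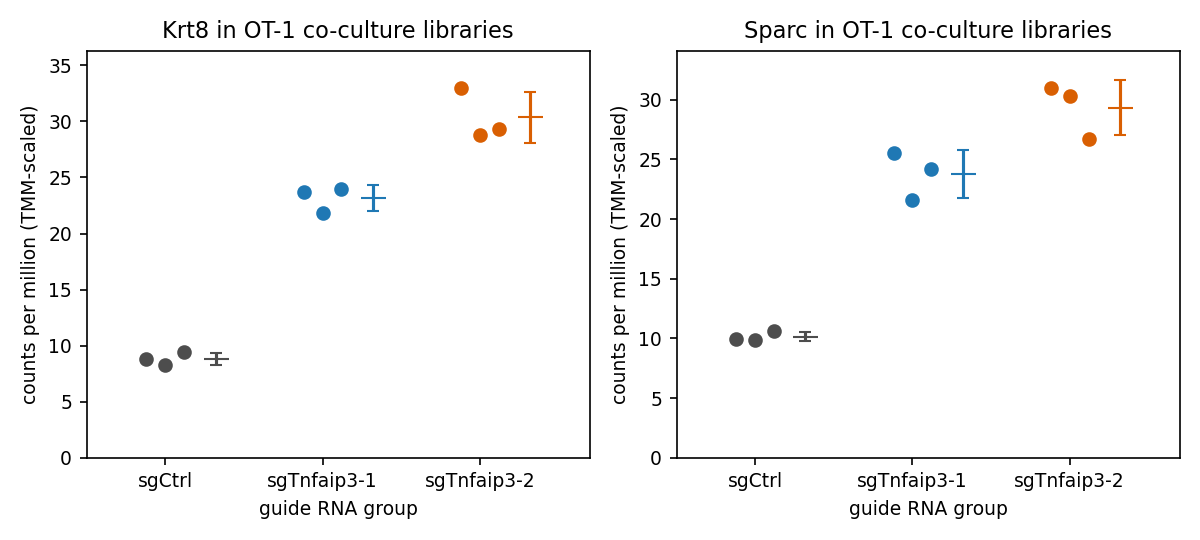
Expression in CPM of Krt8 (left) and Sparc (right) in the 9 co-cultured OT-1 libraries by guide, with each point 1 library and the bars the mean and SD of 3. Krt8 lies between 21.8 and 33.0 CPM in the libraries labelled knockout and between 8.28 and 9.40 CPM in the controls.

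The OT-1 guides differed from each other in expression. Relative to sgTnfaip3-1, sgTnfaip3-2 libraries had more Arc (log2 1.08, SE 0.183), a regulator of the neuronal cytoskeleton, more of the sugar transporter Slc2a6 (log2 1.02, SE 0.157) and more Nphs1 (log2 0.96, SE 0.277). They had less of the mitochondrial gene mt-Nd3 (log2 -3.05, SE 0.794) and of the zinc-finger genes Zfp943 (log2 -1.25, SE 0.325) and Zfp81 (log2 -1.16, SE 0.145), whose families share similar sequence. The share of mitochondrial genes was 0.346% to 0.916% with sgTnfaip3-2 and 1.24% to 1.35% with sgTnfaip3-1. The fall of mt-Nd3 went in the same direction as this share but was larger than the difference in share. edgeR called 1332 genes higher and 1305 lower of 13380, 2637 in all. The difference correlated with transcript GC content across genes (rho 0.73), and with the GC correction 496 genes were called, 350 of them among the 2637. Nphs1 (adjusted p = 0.139), mt-Nd3 (0.078), Zfp943 (0.0742) and Zfp81 (0.102) were not called with that correction, while Arc (log2 0.76, adjusted p = 0.0308) and Slc2a6 (log2 0.73, 0.0177) were. The count was 4049 and 1610 without sgCtrl replicates 1 and 2, 202, 34 and 69 without sgTnfaip3-1 replicates 1, 2 and 3, 1552 and 249 without sgTnfaip3-2 replicates 1 and 3, and 4441 without sgCtrl replicate 1 and sgTnfaip3-2 replicate 1 together. The calls of Nphs1, mt-Nd3 and Zfp943 were lost without sgTnfaip3-1 replicate 1, 2 or 3 or sgTnfaip3-2 replicate 3, that of Arc without sgTnfaip3-1 replicate 2 or 3, that of Slc2a6 without sgTnfaip3-1 replicate 2 and that of mt-Nd3 without sgTnfaip3-2 replicate 1, with adjusted p between 0.0547 and 0.116. With the replicate block those of Nphs1, Zfp943 and mt-Nd3 were lost (0.0517 to 0.0647), and with the GC correction and the block that of Slc2a6 as well (0.0507).

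Besides the mitochondrial share, the sum of the low-control genes of a list of adherent-cell genes differed between the guides, at 158 to 175 CPM with sgTnfaip3-2 and 144 to 148 CPM with sgTnfaip3-1, so the changes of gene groups here moved with both. Cell-cycle genes were higher with sgTnfaip3-2 than with sgTnfaip3-1, 8 of 24 called higher and 0 lower, and 11 and 1 when adjusted over the list alone (camera adjusted p = 1.67e-05, and 0.0325 with an estimated correlation). Another 4 lists were called by camera at its preset correlation but not with an estimated one. Of interferon-response genes 6 of 30 were higher and 0 lower (12 and 0 when adjusted over the list alone, camera adjusted p = 0.0178, but adjusted p = 0.145 with an estimated correlation). Of NF-kB targets 8 of 27 were higher and 2 lower (10 and 3 when adjusted over the list alone, camera 0.0178, but adjusted p = 0.263 with an estimated correlation). Of MHC class I genes 5 of 21 were higher and 1 lower (6 and 2 when adjusted over the list alone, camera 0.0288, but adjusted p = 0.5 with an estimated correlation, 0.0822 by camera with the GC correction and 0.0662 by fry). Of cytotoxic and effector genes 3 of 24 were higher and 10 lower (3 and 10 when adjusted over the list alone, camera 0.0219, but adjusted p = 0.263 with an estimated correlation, and 0.0772 by camera with the GC correction). With that correction the interferon list passed with an estimated correlation too (adjusted p = 0.0307), and 4 further lists were called lower with sgTnfaip3-2. Of p53 targets 0 of 19 were then higher and 5 lower (0 and 7 when adjusted over the list alone, camera 4.34e-05, and 0.0282 with an estimated correlation). Of IL-2 and STAT5 genes 0 of 21 were higher and 6 lower (0 and 7 when adjusted over the list alone, camera 5.04e-06, but adjusted p = 0.196 with an estimated correlation). Of inhibitory receptors 0 of 18 were higher and 2 lower (1 and 5 when adjusted over the list alone, camera 0.0166, but adjusted p = 0.196 with an estimated correlation). Of activation receptors 0 of 21 were higher and 3 lower (2 and 4 when adjusted over the list alone, camera 0.032, but adjusted p = 0.374 with an estimated correlation). Against the control alone, Ifng rose by 1.28 on the log2 scale with sgTnfaip3-1 and by 1.19 with sgTnfaip3-2, and Krt8 by 1.39 and 1.78. Of 20 cytokine and chemokine genes, 13 rose with sgTnfaip3-1 and 15 with sgTnfaip3-2 (16 and 15 when adjusted over the list alone), with 0 lower. The camera adjusted p was 2.96e-22 and 1.85e-09, and 0.0131 and 0.0392 with an estimated correlation. Of the lists camera called with 1 guide only, IL-2 and STAT5 genes were higher with sgTnfaip3-1, 6 of 21 higher and 2 lower (8 and 4 when adjusted over the list alone, camera 0.0151, but adjusted p = 0.252 with an estimated correlation). With sgTnfaip3-2, 10 were higher and 7 lower, also when adjusted over the list alone (camera 0.41, upward), and with the GC correction 5 and 7 (5 and 8 when adjusted over the list alone, camera 0.845, downward). CD4+ T-cell markers were lower with sgTnfaip3-1, 0 of 4 higher and 1 lower (0 and 2 when adjusted over the list alone, camera 0.0374, but adjusted p = 0.176 with an estimated correlation, against camera 0.41). MHC class I genes were higher with sgTnfaip3-2, 14 of 21 higher and 3 lower (15 and 3 when adjusted over the list alone, camera 0.0101, but adjusted p = 0.443 with an estimated correlation, against camera 0.141 with sgTnfaip3-1). With sgTnfaip3-1 there were 958 genes higher and 573 lower (1531), and with sgTnfaip3-2 there were 3330 higher and 3181 lower (6511). With the GC correction these counts were 2405 and 5083. Of the original calls, 1490 of 1531 and 3577 of 6511 were kept in the same direction. The shared genes given next were counted without that correction. Both guides shared 877 higher and 431 lower genes, where independent lists would share 238 and 136, and 5 genes were called in opposite directions. The log2 changes correlated at 0.76 across genes against 0.49 in 20 simulations with no effect, with a covariance of 0.21 against 0.0289, and part of the overlap may come from the 3 shared controls. Those simulations held no GC trend, while the changes of both guides followed GC content (rho 0.23 with sgTnfaip3-1 and 0.62 with sgTnfaip3-2). A bias shared by the libraries could thus also raise both values. The sgTnfaip3-1 count was 839 without sgCtrl replicate 2, 707, 739 and 727 without sgTnfaip3-1 replicates 1, 2 and 3, and 2400 without sgTnfaip3-2 replicate 1.

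**Figure D5:**
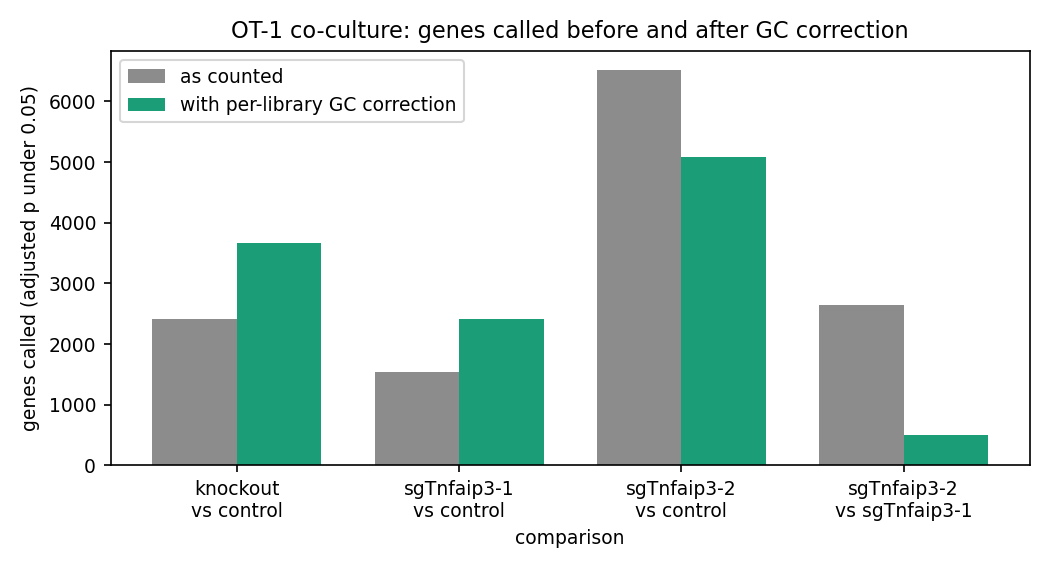
Number of genes called by edgeR at an adjusted p under 0.05 in each OT-1 comparison, as counted (grey) and with a per-library correction for GC content (green). The count between the guides is 2637 as counted and 496 with the correction.

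The title of the series speaks of targets that act in both cell kinds, so the calls of A549 and OT-1 were compared over the 9477 genes with the same symbol tested in both. Genes higher in both sets labelled knockout numbered 11, where independent lists would share 5.52 (odds ratio 2.33, 95% interval 1.06 to 4.72, Fisher's exact test two-sided p = 0.0204, adjusted over the 2 directions 0.0408). They included the chemokine CCL5 (log2 2.50 in A549 and 0.67 in OT-1), the scavenger receptor OLR1 (1.77 and 0.96), the prostaglandin synthase PTGS2 (0.67 and 1.28), the chemokine CXCL1 (0.50 and 1.35), SOD2 (0.60 and 0.34) and the growth factor AREG (0.37 and 1.5). CDC42EP3 (-0.36 and -0.55) and S1PR3 (-0.29 and -0.32) were lower in both, 2 genes where 2.53 would be shared by independent lists (Fisher's exact p = 1). Another 17 were called in opposite directions, against 13 in the same direction, and the count of 17 was not tested. Most of the 17 were lower in A549 and higher in OT-1. Genes higher in OT-1 thus included A549 calls of both directions, so the overlap upward does not by itself show a shared direction. Among the 17 were SPARC (-0.56 and 1.39) and KRT8 (-0.28 and 1.60). In OT-1 these 2 are markers of other cells, which rose together in those libraries, so the values do not show a change in the T cells. The OT-1 values of the genes higher in both sets come from the same libraries. For these genes too the counts do not show which cells made the mRNA. Across all shared genes the log2 changes correlated at r = -0.09 and rho = -0.15. The overlap upward did not pass with the GC correction in OT-1 (12 genes, adjusted p = 0.212), with DESeq2 (22 genes, 0.103) or at an unadjusted p under 0.05 in both (108 genes, 0.065). The call of CDC42EP3 in A549 was lost without any 1 of the 9 libraries, and those of AREG, S1PR3 and KRT8 without sgCtrl replicate 1 or 3. With the replicate block all 4 were lost, with adjusted p between 0.0605 and 0.151. In OT-1 the call of Sod2 was lost without sgCtrl replicate 1 (adjusted p = 0.0722) and that of Olr1 without sgCtrl replicate 2 (adjusted p = 0.0877).

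The authors' deposited table for A549 listed 117 genes higher and 105 lower at an adjusted p under 0.05, 136 of these 222 also called by edgeR here, and the log2 changes of the authors' deposited table and edgeR correlated at 0.863 across genes. For OT-1 the authors' deposited table listed 1412 higher and 1038 lower, 1861 of these 2450 also called by edgeR here, with a correlation of 0.948.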

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

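The tests of GC content and of the guides after GC correction were chosen only after the count between the OT-1 guides had been seen, and the simulations of a hidden factor after the splits; the other splits of the libraries were planned.

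Outliers among the 6 libraries labelled knockout were sought in 35 sets of values. These were the targeted genes, the largest changes, library totals and shares, and the sum of adherent-cell genes. In 3 of the 35, all of them genes, a library's gap to its nearest neighbour, divided by the range, exceeded Dixon's 95% critical value, where chance gives about 1 in 20. ID4 was at 13.7 CPM in sgTNFAIP3-1 replicate 2 and between 10.5 and 11.2 CPM in the other 5 (ratio 0.757). Nav3 was at 6.34 CPM in sgTnfaip3-2 replicate 2 and between 7.20 and 7.67 CPM elsewhere (ratio 0.647). Klrb1b was at 3.16 CPM in sgTnfaip3-2 replicate 1 and between 4.26 and 4.65 CPM elsewhere (ratio 0.738).

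Without the GC correction, the OT-1 guides differed in 4 of the reported genes with the largest changes. With that correction 350 of the 2637 calls between the guides were kept, so these 4 values carry that limit. Relative to sgTnfaip3-1, sgTnfaip3-2 libraries had less Il24 (log2 -0.51, edgeR adjusted p = 0.0356) and Arrdc3 (log2 -0.62, 0.0307) and more Tinagl1 (log2 0.60, 0.00897) and Flnc (log2 0.45, 0.00876).

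In all, edgeR called 2637 genes between the OT-1 guides. A GC content bias between libraries may account for most of them, and a per-library GC correction lowered the count by 81.2%. That correction takes out any trend with GC content, also one that comes from the guides, so the fall does not tell the 2 apart. Libraries of the same guide also parted by GC content with sgTnfaip3-2 (rank correlations of their deviations 0.63, -0.62 and -0.3). With sgTnfaip3-1 they did so little (0.15, -0.12 and -0.03). After the correction 3.71% of the genes tested were still called, 496 in number, with 0 in any of the other 9 splits of the 6 libraries, which are too few for a share under 0.05. A difference between the guides may account for these, and whether it lies in the cutting sites, in the share of edited cells or in the handling of the cultures was not tested. Before the correction the count was 34, 69 and 202 without sgTnfaip3-1 replicates 2, 3 and 1, so it depends on single libraries, and the corrected count was not refitted without them.

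For A549 knockout against control, 2 of the 84 splits of the 9 libraries, the real one included, called as many genes as the 170 of the labels, a share under 0.05. This count treats the 9 libraries as interchangeable, while they came in 3 guide groups whose replicates may be technical. It therefore does not exclude a random difference between those groups. A hidden factor is not excluded either, since 1 of 20 simulations with such a factor and no effect called at least 170. The other split set sgCtrl replicate 2 and sgTNFAIP3-1 replicates 1 and 3 apart and called 3347 genes, many times the real count, which points to a structure of the samples that the labels do not name. In OT-1 2 of 84 splits called as many as 2412, and the other, with 4493, set the sgTnfaip3-2 libraries apart from the rest. GC content also sets these apart (rank correlations of 0.38 to 0.75, against -0.54 to -0.29 in the other 6), and this split was not run with the GC correction, so whether it reflects the guide was not tested. With 3 libraries against 3 the 10 splits are too few for a share under 0.05. The real and highest other values were 187 and 3528 for sgTNFAIP3-1 (2 splits as large, the other again a structure, with sgTNFAIP3-1 replicate 2 beside sgCtrl replicates 1 and 3) and 109 and 1 for sgTNFAIP3-2 (1 split). They were 0 and 1 between the A549 guides (10 splits, with 1273 genes at an unadjusted p under 0.05 by edgeR and 14 called by DESeq2). In OT-1 they were 1531 and 1 for sgTnfaip3-1, 6511 and 1 for sgTnfaip3-2 and 2637 and 0 between the guides (1 split each).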

How the results depend on the processing

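The GC correction, the fit without mitochondrial and ribosomal RNA genes, the omission of sgCtrl replicate 1 with sgTnfaip3-2 replicate 1, and the covariate were chosen after seeing the data; the other settings were planned. No named gene or list that was called changed direction. The balance of higher and lower genes did change in some counts. It went from 80 higher and 90 lower to 259 and 188 in A549 knockout and from 75 and 112 to 1297 and 822 for sgTNFAIP3-1, both without sgCtrl replicate 2. It went from 3330 and 3181 to 2469 and 2895 for sgTnfaip3-2 without its replicate 3, and from 1332 and 1305 to 1494 and 1682 between the OT-1 guides with DESeq2. Of the values of named genes under other settings, 2542 kept their side of the threshold, 254 lost it and 19 gained it, and of those of gene lists 1034 kept it, 58 lost it and 39 gained it. Another 9 and 46 changed sign without passing in either setting. DESeq2 size factors left every count of genes within 1.5 times, as did the fit without mitochondrial and ribosomal RNA genes in OT-1. The cause was not tested for any change below, except that a lower threshold gives fewer calls by construction. Leaving out a library lowered some counts and raised others.

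In A549, knockout against control called 170 genes, and 294 with DESeq2, 72 at a threshold of 0.01 and 571 with the covariate. Leaving out single libraries gave 64 to 447. For sgTNFAIP3-1 the count of 187 was 475 without a filter, 287 with DESeq2, 67 at 0.01, 1669 with the covariate and 64 to 2119 without single libraries. For sgTNFAIP3-2 the count of 109 was 330 without a filter, 192 with DESeq2, 40 at 0.01, 702 with the covariate and 35 to 276 without single libraries. Between the guides the count of 0 by edgeR was 121 without a filter, 14 with DESeq2, 1030 with the covariate and 0 to 46 without single libraries, and 1273 genes had an unadjusted p under 0.05. Without sgCtrl replicate 2, 159 of the original 170 genes were still called among 447, and with DESeq2 169.

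In OT-1, knockout against control called 2412 genes, and 782 at 0.01, 4860 with the mean of the guide effects, 3662 with the GC correction and 1407 without sgCtrl replicate 1 and sgTnfaip3-2 replicate 1, 1269 of them among the 2412. Single libraries gave 913 to 2932. For sgTnfaip3-1 the count of 1531 was 583 at 0.01, 2405 with the GC correction, 2860 without both libraries and 707 to 2400 without single ones. For sgTnfaip3-2 the count of 6511 was 3889 at 0.01 and 5364 to 6509 without single libraries. Between the guides the count of 2637 was 141 at 0.01, 496 with the GC correction, 4441 without both libraries and 34 to 4049 without single ones.

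Whether replicate numbers pair the samples stays open. Only 3 of 9 A549 and 1 of 9 OT-1 libraries correlated best with a library of their own number, but libraries of the 2 A549 target guides with the same number correlated at 0.25, 0.44 and 0.22. Control and target libraries of the same number correlated at -0.69 to -0.06 in A549, and all pairs of the same number at -0.37 to 0.20 in OT-1. With a replicate block the counts were 79, 76 and 39 in A549 and, in OT-1, 1204 for knockout, 947 for sgTnfaip3-1 and 611 between the guides (172 with the GC correction as well), and 5 genes were called in both cell kinds. That overlap of 13 was 173 at an unadjusted p under 0.05 and 30 with DESeq2.

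With an estimated correlation the number of gene lists called fell from 8 to 4 (A549 knockout), 7 to 2 (sgTNFAIP3-2), 2 to 0 (A549 guides, 1 by fry and 1 with the replicate block), 8 to 2 (OT-1 knockout), 9 to 3 (sgTnfaip3-1), 8 to 3 (sgTnfaip3-2, 15 by fry) and 5 to 1 (OT-1 guides, 10 by fry). Lists called without single libraries numbered 6 to 9 in A549 and 7 to 9 in OT-1. The comparison of co-cultured with untreated cells and the fit of all 12 OT-1 libraries were not run. Genes near 0.166 CPM in A549 or 0.165 CPM in OT-1 lie at the limit that depth sets.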

Other observations

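All tests in this part except those of cancer-cell RNA and of GC content in the second list were chosen only after the result was seen.

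Genes of adherent cells beyond the markers above were also higher in the OT-1 libraries labelled knockout. A second list of 45 such genes, none of them in the lists above, was written after the keratin and matrix markers had been seen and before the values of its own members were looked at; Thbs1 alone had been named already. Of its members 34 were expressed highly enough to be tested. Among the 25 with less than 10 CPM in the controls, 23 were higher and 22 called higher, with 0 called lower and a median log2 change of 1.28 (quartiles 0.98 and 1.66). Examples are the secreted glycoprotein Fstl1 (log2 2.15, SE 0.227), the growth factor receptor Egfr (log2 2.01), the collagen Col6a1 (log2 1.93) and the endocytic receptor Lrp1 (log2 1.78), while Cav2 (log2 0.39), Fzd1 (log2 -0.16) and Nid2 (log2 -0.70) were not called. The median was 1.11 with sgTnfaip3-1 and 1.42 with sgTnfaip3-2. The limit of 10 CPM was set after the prediction was written and before the values were seen. With limits of 5 and 20 CPM the medians were 1.39 and 1.24, and 1.02 over all 34, of which 30 were higher. Summed over these 25 alone, expression was between 65.4 and 72.7 CPM in the controls and between 144 and 175 CPM in the libraries labelled knockout.

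RNA of the co-cultured cancer cells may account for these genes and for Krt8 (8.82 and 26.8 CPM) and Sparc (10.1 and 26.6 CPM). The second list had to have a median over 0.7 and had 1.28. Expression by the T cells could meet that bound too, so it does not tell the 2 apart. Members with low control levels, such as Egfr (0.377 and 1.53 CPM), could pass the filter through the libraries labelled knockout alone, which favours rises. A GC content bias is argued against by the median of 1.16 (quartiles 1.02 and 1.44) after the GC correction. Expression by the T cells may also account for these genes. The folds of the members differed beyond their errors (heterogeneity of 10 per degree of freedom), and 0 of the 25 lay under the limit of detection in the controls. RNA from a single source added to differing T-cell levels would also give differing folds. Expression by the T cells does not require absence in the controls. Neither value tells the causes apart, so this stays open. Whether RNA of cancer cells also adds to the cytokine and chemokine genes was not tested. The descriptions of the co-cultured libraries speak of a sort without giving a gate, the cancer cells are not named, and no library of cancer cells alone was at hand to set their share. Of the 34 members 9 stood at 10 CPM or more in the controls. Among these 9, Yap1 (log2 0.78), Axl (log2 0.71) and Epha2 (log2 0.68) were called higher. The rest were not called, with log2 changes from -0.20 to 0.27. The median of 1.28 thus holds only for members with low control levels.

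The higher TNFAIP3 mRNA in the A549 libraries labelled knockout was weighed as well. A swap of single libraries is argued against by the mean of the NF-kB target list, in which 0 of the 6 libraries labelled knockout lay in the control range (log2 of CPM plus 1 between 5.13 and 5.22, against 4.67 to 4.72), though a reversal of whole groups is not excluded by this. TNFAIP3 is itself a gene that NF-kB induces, and its log2 change of 0.543 lay between the quartiles of that list (0.278 and 0.814), which does not hold TNFAIP3. TNFAIP3 transcription may thus follow NF-kB activity, but many members of any list lie between its quartiles, so this is weak support. The cut site and the protein were not measured here.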
